A study of Mus musculus with 16 samples.

How the data were processed

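Dorsal root ganglia (L1, L2, L6, S1 and S2) were taken on day 16 from 16 C57BL6/J mice that had received 100 µL of saline with or without 6.41 nM VEGF165 in the bladder on days 1, 5 and 9. According to the labels, poly(A) libraries were made from 300 ng of RNA per animal and sequenced with paired ends on a NovaSeq instrument. The labels name Partek, Bowtie2, STAR and HTSeq and the genome build mm39, without versions and without saying what each tool did. The von Frey measurements of the animals were not used here.

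The deposited table gives counts per M (mega) reads (CPM), as the authors computed them, for 55357 Ensembl genes in 16 libraries. Each column was checked to sum to the total that the unit requires. Within each library the values were multiples of a smallest step, and division by this step gave whole reads (99.8101 to 99.9149% of the values above 0 lay within 0.1 read of a whole number). The recovered totals were 25.16 to 41.2 M reads per library, 25.16 to 32.8 in batch 1 and 32.83 to 41.2 in batch 2. No 2 libraries were copies of each other (log2 correlations from 0.9079 to 0.9839, smallest chi-square per degree of freedom 23.9). Of the genes listed, 42 shared their symbol with another gene and 12 had none, and these were referred to by their Ensembl identifier. Transcript length and GC content were taken by gene identifier from the GENCODE M21 transcripts, of an older build than the table's, and were found for 14949 of 14962 tested protein-coding genes (99.91%).

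Libraries were grouped by the treatment and sex in their labels, 4 per group, with 2 libraries of each group in each of 2 batches. In batch 1 the numbers in the library names formed 2 runs, VEGFA males with saline females and saline males with VEGFA females. What these runs mean is not given, and they were not modelled. Genes with a mean of at least 0.5 CPM over all libraries were tested (18283), and 37074 were left out. Values of log2(CPM + 0.5) were fitted in limma 3.58.1 (R 4.3.3) with 4 group coefficients and a batch coefficient over all 16 libraries, with eBayes and a trend, and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. The 6 comparisons were VEGFA with saline in males, in females and over both sexes, the female minus the male difference, and females with males in saline and in VEGFA animals. The median standard error of a log2 difference was 0.239 within a sex or treatment, 0.169 over both sexes and 0.337 for the female minus male difference. Differences within each batch were computed from 2 against 2 libraries.

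The pipeline was tested on simulated data with the dispersions of these libraries and 250 changed genes per fold over 5 runs. The changed genes of all folds were present together and had a mean of at least 1 CPM. Genes varied independently, and the batch effect was the same in all groups. For the male comparison the pipeline recovered 8% of genes at 1.5-fold, 41.6% at 2-fold, 85.6% at 4-fold and 90.4% at 8-fold, all in the right direction, and 4.24% of calls were false.

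Gene lists (47) of cell types, pathways and neighbouring tissues were tested with camera of limma with a preset correlation between genes of 0.01, and beside it with an estimated correlation and with fry, each adjusted over the lists of a comparison. The lists of mitochondrially encoded genes, cytosolic ribosomal proteins and replication-dependent histones had been set up as signs of RNA quality. A list needed at least 5 tested members, which left 46; the Y-linked list with 4 was given by its genes. Genes of a list were also adjusted over the list alone, and the lists are described by their median log2 difference and the number of members on each side. The list tests of the 2 sex comparisons were not among the results planned.

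Groups, comparisons, tests, lists, the rule for naming genes and the first set of alternatives were fixed before the data were examined. Under the rule, a comparison names up to 12 genes with the largest rise and up to 12 with the largest fall that passed, had a mean of at least 1 CPM, an official symbol and the same sign in both batches. Where fewer than 10 genes passed, the 6 highest and 6 lowest by unadjusted p were added. Up to 4 members of each list with the smallest p, Vegfa, Flt1, Kdr, Nrp1 and Nrp2, and in the sex comparisons Xist, Ddx3y, Uty, Kdm5d and Eif2s3y were always eligible. The text names a part of these genes, chosen after their values were seen.

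The alternatives were a pseudocount of 0.1 or 1 CPM, no filter or a mean of at least 2 CPM, median-of-ratios scaling, no batch covariate, either batch alone, only the libraries of the comparison, eBayes without trend or robust, array weights, each library left out in turn, and edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 on the recovered reads with batch as a covariate. Chosen later were a correction of each library for a linear trend on log2 transcript length and GC content, the muscle and spinal cord list means as covariates, leaving out VEGFA males 1 and 2 or 5 and 6, and a term for a batch-dependent VEGFA difference within each sex.

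Males and females of a treatment share replicate numbers, so that a pairing by number was checked from the correlation of the deviations of same-numbered libraries from their group means. In saline animals it was 0.37, 0.266, 0.375 and 0.173 for numbers 3, 4, 7 and 8, and the sex comparison was repeated with the number as a block in place of batch, which gave 8 genes past the threshold against 9. The list tests in saline animals were repeated with this block after the data were seen. VEGFA and saline animals share no number, so no paired test applied to treatment.

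List means per library were compared by exact permutation over 70 arrangements in 6 tests of 2 lists, chosen after the data were seen. The interferon list was tested between treatments within each sex and between sexes within each treatment. The nerve injury list was tested between treatments within each sex only. Comparisons were repeated for other splits of the same libraries, all 35 where 2 groups were compared and 100 drawn with a fixed seed otherwise. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.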

Results

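Lumbosacral dorsal root ganglia of C57BL6/J mice were profiled by poly(A) RNA sequencing on day 16, after instillation of VEGF165 or saline into the bladder on days 1, 5 and 9. The series held 16 libraries, each from 1 animal, in 4 groups of 4 (saline males, VEGFA males, saline females and VEGFA females). Each group had 2 libraries in batch 1 and 2 in batch 2, and the libraries held 25.16 to 41.2 M (mega) counted reads. Levels are given in counts per M reads (CPM) as mean and SD of 4 libraries, and differences as log2 values with their standard error (SE) from limma with batch as a covariate.

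Angptl4, which codes for a secreted inhibitor of lipoprotein lipase, lay lower in the VEGFA animals of both sexes and had the smallest p-value of the comparison over both sexes. Its level was 39.5 CPM (SD 3.10) in saline males and 25 (SD 2.95) in VEGFA males. In females it was 45.8 CPM (SD 9.37) in saline and 25.2 CPM (SD 5.63) in VEGFA animals. The log2 difference was -0.75 (SE 0.121, 95% CI -1.01 to -0.50, n = 4 per group), with -0.95 in batch 1 and -0.55 in batch 2. Angptl4 did not pass the threshold (adjusted p = 0.16 by limma). In VEGFA males Angptl4 ranged from 21.6 to 28.7 CPM and in saline males from 36.6 to 43.5 CPM. The ranges were 20.8 to 33.3 CPM in VEGFA females and 35.6 to 57.1 CPM in saline females.

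Sfrp4, which codes for a secreted antagonist of Wnt signalling, also lay lower in VEGFA animals (log2 difference -0.73, SE 0.127, adjusted p = 0.22 by limma), by -0.64 in batch 1 and -0.81 in batch 2. Its means were 63.9 CPM (SD 14.7) in saline males against 40.9 (SD 7.47) in VEGFA males. In females they were 156 CPM (SD 27.2) in saline against 88.9 CPM (SD 22.9) in VEGFA animals. Ryr3, a ryanodine receptor gene, lay higher (log2 difference 0.94, SE 0.178, adjusted p = 0.35), by 1.33 in batch 1 and 0.55 in batch 2. It stood at 3.42 CPM (SD 2.04) and 6.38 CPM (SD 2.26) in saline and VEGFA males and at 3.10 (SD 2.14) and 5.73 (SD 1.29) in females. Angptl4 (ENSMUSG00000002289), Sfrp4 (ENSMUSG00000021319) and Ryr3 (ENSMUSG00000057378) lie on chromosome 17 at 33992724 to 34000804, chromosome 13 at 19807274 to 19817164 and chromosome 2 at 112461700 to 113047441 of build mm39, per the submitters' processing notes.

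**Figure D1:**
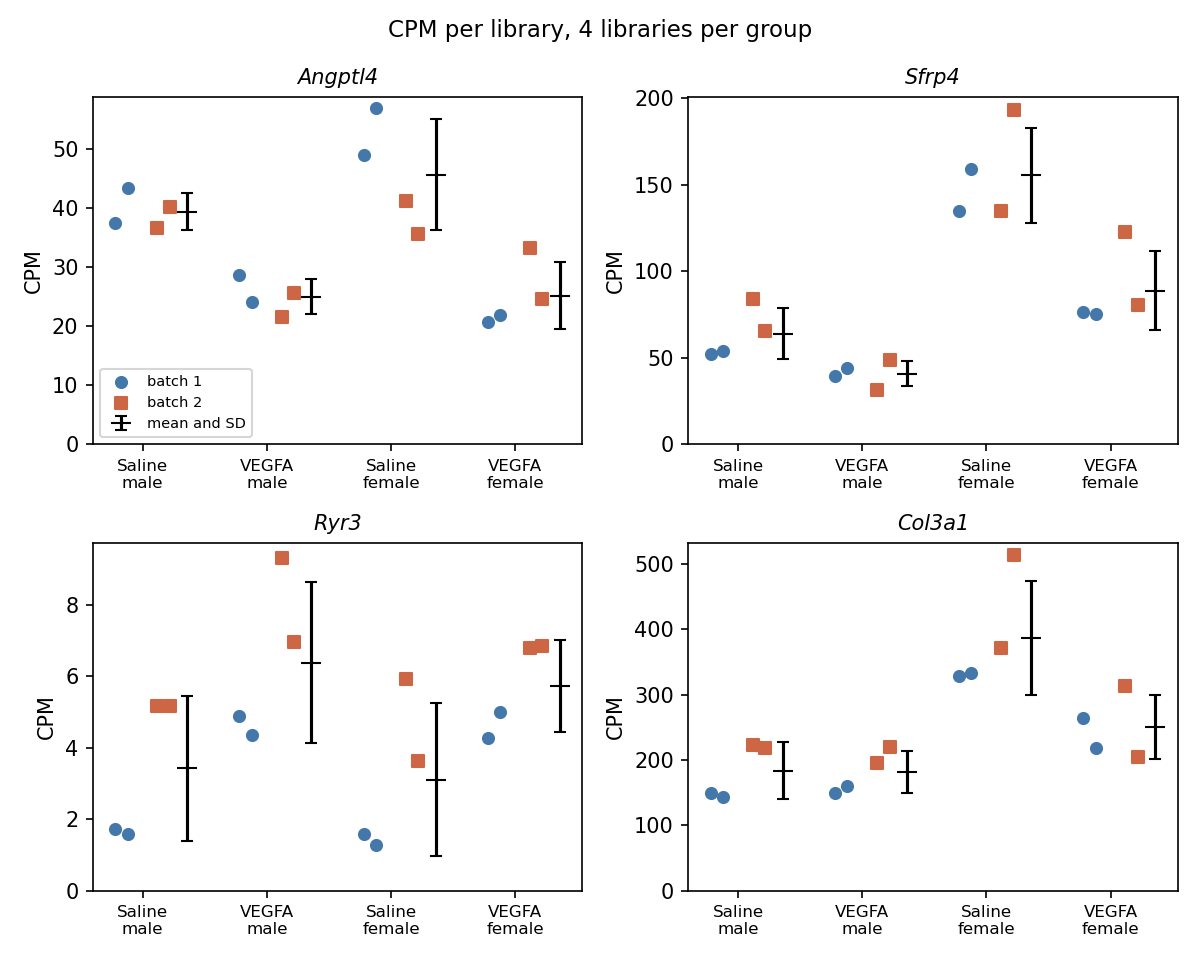
CPM of Angptl4, Sfrp4, Ryr3 and Col3a1 in each library, by group and batch, with the mean and SD of the 4 libraries of a group. None of the 4 genes passed the threshold between VEGFA and saline in limma.

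Over both sexes 0 of 18283 genes passed an adjusted p of 0.05 in limma, and 1164 had an unadjusted p under 0.05 (625 higher and 539 lower) where 914 would be expected by chance. edgeR called 0 genes and DESeq2 called 4, which were Angptl4, Sfrp4, Ryr3 and Gm20008, the last a name taken up after the values were seen. Next in order, all with an adjusted p of 0.72 in limma, were Retreg3 (log2 difference -0.38, SE 0.0842), Lbp (-0.50, SE 0.113), Slx4ip (0.80, SE 0.197), Hook1 (1.03, SE 0.252), Mid2 (0.63, SE 0.16), Sdad1 (0.48, SE 0.121) and Frmpd4 (0.67, SE 0.172). Among genes of the lists with the same adjusted p, the complement gene C1qc (-0.51, SE 0.144), the matrix gene Fbln1 (-0.51, SE 0.14) and the mast cell protease Mcpt4 (-0.58, SE 0.185) lay lower. The potassium channel genes Kcna1 (0.67, SE 0.221) and Kcnma1 (0.34, SE 0.111) and the cation channel gene Trpm3 (0.43, SE 0.144) lay higher.

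The mRNA of the instilled factor's own gene and those of its receptors were measured without a difference past the threshold. Over both sexes the log2 differences were 0.14 for Vegfa (SE 0.188, adjusted p = 0.84 by limma), 0.14 for Flt1 (SE 0.103, adjusted p = 0.74), 0.17 for Kdr (SE 0.263, adjusted p = 0.86), -0.08 for Nrp1 (SE 0.0959, adjusted p = 0.81) and 0.22 for Nrp2 (SE 0.115, adjusted p = 0.72). Leaving out 1 library gave 0.05 to 0.24 for Vegfa, 0.06 to 0.18 for Flt1 and 0.04 to 0.34 for Kdr. It gave -0.13 to -0.04 for Nrp1 and 0.17 to 0.28 for Nrp2. In males they were -0.08 for Vegfa (SE 0.266, 95% CI -0.64 to 0.48), 0.03 for Flt1 (SE 0.145), -0.06 for Kdr (SE 0.372), -0.10 for Nrp1 (SE 0.136) and 0.21 for Nrp2 (SE 0.162), with adjusted p-values from 0.94 to 0.99. In females they were 0.35 for Vegfa (SE 0.266, adjusted p = 0.59), 0.25 for Flt1 (SE 0.145, adjusted p = 0.53), 0.40 for Kdr (SE 0.372, adjusted p = 0.66), -0.06 for Nrp1 (SE 0.136, adjusted p = 0.87) and 0.22 for Nrp2 (SE 0.162, adjusted p = 0.59). With 1 library left out, the female differences ran from 0.20 (without VEGFA female 1) to 0.55 (without VEGFA female 6) for Vegfa and from 0.10 (without VEGFA female 2) to 0.33 for Flt1. They ran from 0.13 (without VEGFA female 2) to 0.61 (without VEGFA female 6) for Kdr, and from 0.12 (without VEGFA female 1) to 0.35 (without VEGFA female 6) for Nrp2. As a list, the 17 VEGF ligands and receptors had medians of 0.11 over both sexes, 0.02 in males and 0.18 in females, with adjusted p of 0.396, 0.991 and 0.306 in limma's camera.

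Cytosolic ribosomal protein genes lay lower over both sexes, with 52 of 57 members below the saline level (median -0.19, with -0.05 in batch 1 and -0.32 in batch 2, adjusted p = 2.66e-10 by camera). This list had been set up as a sign of RNA quality. The slope of expression on transcript length ran from 0.142 to 0.235 in VEGFA and from -0.00971 to 0.183 in saline animals of batch 2. In batch 1 it ran from -0.288 to 0.042 in VEGFA and from -0.229 to -0.102 in saline animals. All 15 antigen presentation genes lay lower (median -0.27, with -0.19 in batch 1 and -0.39 in batch 2, adjusted p = 2.47e-06), as did all 17 macrophage genes (median -0.25, with -0.19 and -0.38, adjusted p = 8.82e-05). Nuclear oxidative phosphorylation genes (median -0.10, 37 of 40 lower, adjusted p = 9.73e-05), fibroblast and collagen genes (-0.20, 15 of 18 lower, with 0.02 in batch 1 and -0.44 in batch 2, adjusted p = 0.000156), adipocyte genes (-0.51, adjusted p = 0.00729), interferon-stimulated genes (-0.19, 21 of 25 lower, adjusted p = 0.00742) and mast cell genes (-0.40, 6 of 6 lower, adjusted p = 0.0103) also lay lower. Glucocorticoid-responsive genes had a median of -0.20 (15 of 16 lower, adjusted p = 0.00134), with -0.59 in batch 1 and 0.14 in batch 2. Skeletal muscle genes (median 0.66, 17 of 17, adjusted p = 3.03e-06) and voltage-gated sodium channel genes (0.09, 12 of 14, adjusted p = 0.0297) lay higher. Each of these 11 lists had an adjusted p = 0.827 with an estimated correlation, and 0 lists passed by that test or by fry. With 1 library left out, the skeletal muscle median was 0.33 without Saline female 4 and 0.42 without VEGFA male 5, the macrophage median -0.17 without Saline female 3 and the fibroblast median -0.10 without VEGFA female 6. The oxidative phosphorylation median was -0.06 without VEGFA female 1 or VEGFA male 6 and -0.07 without VEGFA male 5. The adipocyte median was -0.33 without Saline female 3 or VEGFA male 6 and -0.18 without Saline male 7. The adipocyte call was lost without Saline female 3, Saline male 7 or VEGFA female 1. The glucocorticoid call was lost without VEGFA female 1 (-0.13), the interferon call without VEGFA male 1 or VEGFA female 6, and the mast cell call without VEGFA female 1 or Saline female 3. The sodium channel median was 0.14 without VEGFA male 1. It lost its call without VEGFA female 1 (0.06), Saline female 3 (0.05), VEGFA male 6 (0.04), Saline male 8 (0.05), VEGFA male 5, VEGFA female 6 or Saline male 7. Adjusted over the list alone, only Angptl4 (glucocorticoid-responsive), C1qc (macrophages), Fbln1 (fibroblasts) and Mcpt4 (mast cells) passed.

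In males, the axoneme gene Cfap74 had the lowest log2 difference among the genes named by p-value (-1.20, SE 0.255), at 4.41 CPM (SD 1.58) in saline and 1.71 (SD 0.912) in VEGFA males. Supt20 stood at 14.6 and 25.3 CPM (log2 difference 0.72, SE 0.175) and Ino80d at 14.7 and 25.1 CPM (0.76, SE 0.185). Ahctf1 (0.88, SE 0.213), Ythdc2 (1.20, SE 0.302) and Pde1a (0.71, SE 0.18) also lay higher. Retreg3 (-0.51, SE 0.119), Gng7 (-0.52, SE 0.127, 32.2 and 22.3 CPM), the clock-linked repressor Nfil3 (-0.92, SE 0.235, 13 and 6.69 CPM) and Angptl4 (-0.65, SE 0.171) lay lower. The interleukin 6 receptor gene Il6ra stood at 10.6 CPM in saline and 5.88 CPM in VEGFA males (-0.83, SE 0.227). The chemokine gene Cx3cl1 was at 36.9 and 16.7 CPM (-1.09, SE 0.359), and mt-Nd3 differed by -0.71 (SE 0.218). All of these genes had an adjusted p of 0.9 in limma.

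In males 0 of 18283 genes passed in limma and 1007 had an unadjusted p under 0.05 (451 higher and 556 lower), against 914 expected. edgeR called 0 genes and DESeq2 called 1, Sox1, a name taken up after the values were seen. With 4 libraries per group, 8% of genes simulated with a 1.5-fold difference, 41.6% with a 2-fold and 85.6% with a 4-fold difference were recovered. The simulation held many large changes, and no trend shared by genes or batch-dependent difference, so these shares may be too high for these data.

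Mitochondrially encoded genes lay lower in VEGFA males (median -0.37, with -0.37 in batch 1 and -0.49 in batch 2, 13 of 13 lower, adjusted p = 3.46e-07 by camera in limma, and adjusted p = 0.793 with an estimated correlation). Genes of nerve injury and regeneration lay higher (median 0.39, 18 of 20 higher, adjusted p = 2.13e-05; adjusted p = 0.793 with an estimated correlation), from -0.09 in batch 1 and 0.98 in batch 2. Sox11 was at 8.13 CPM (SD 1.57) in saline and 17.1 (SD 10.4) in VEGFA males (log2 difference 0.83, SE 0.262, with 0.23 in batch 1 and 1.44 in batch 2). Atf3 stood at 12 (SD 3.99) and 33.8 CPM (SD 29.8), with a log2 difference of 0.92 (SE 0.45, with -0.19 and 2.03), which was 0.51 without VEGFA male 5 and 0.61 without VEGFA male 6. Neither passed, and 0 of the 20 genes passed when adjusted over the list alone. Endothelial genes (median -0.17, 14 of 17 lower, adjusted p = 0.0177; adjusted p = 0.793 with an estimated correlation) lay lower. So did glucocorticoid-responsive genes (-0.23, 13 of 16 lower, with -0.59 in batch 1 and 0.09 in batch 2, adjusted p = 0.00976; adjusted p = 0.793 with an estimated correlation). Interferon-stimulated genes lay higher (0.12, 23 of 25, adjusted p = 0.047; adjusted p = 0.893 with an estimated correlation). Markers of tissues next to the ganglion lay lower, with medians of -1.42 for 15 spinal cord genes (adjusted p = 4.92e-06) and -0.92 for 13 adipocyte genes (adjusted p = 8.42e-06). Both had an adjusted p = 0.793 with an estimated correlation, so that 7 lists passed with the preset correlation and 0 without it or by fry. Single libraries moved these medians. The spinal cord median was -2.29 without Saline male 8 and the injury median 0.17 without Saline male 8 and 0.19 without VEGFA male 6. The adipocyte median was -0.57 without VEGFA male 6 and -0.20 without Saline male 7, where its call was lost. The interferon median was 0.23 without VEGFA male 1 and 0.03 without VEGFA male 2, and its call was lost without VEGFA male 2 or 5 or Saline male 4, 7 or 8. The endothelial median was -0.30 without Saline male 4, -0.10 without VEGFA male 1 and -0.09 without Saline male 7, with the call lost without the last 2 libraries, VEGFA male 6 or Saline male 8. The glucocorticoid median was -0.37 without VEGFA male 1 and -0.43 without Saline male 7, and it lost its call at -0.12 without VEGFA male 2 or Saline male 3.

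**Figure D2:**
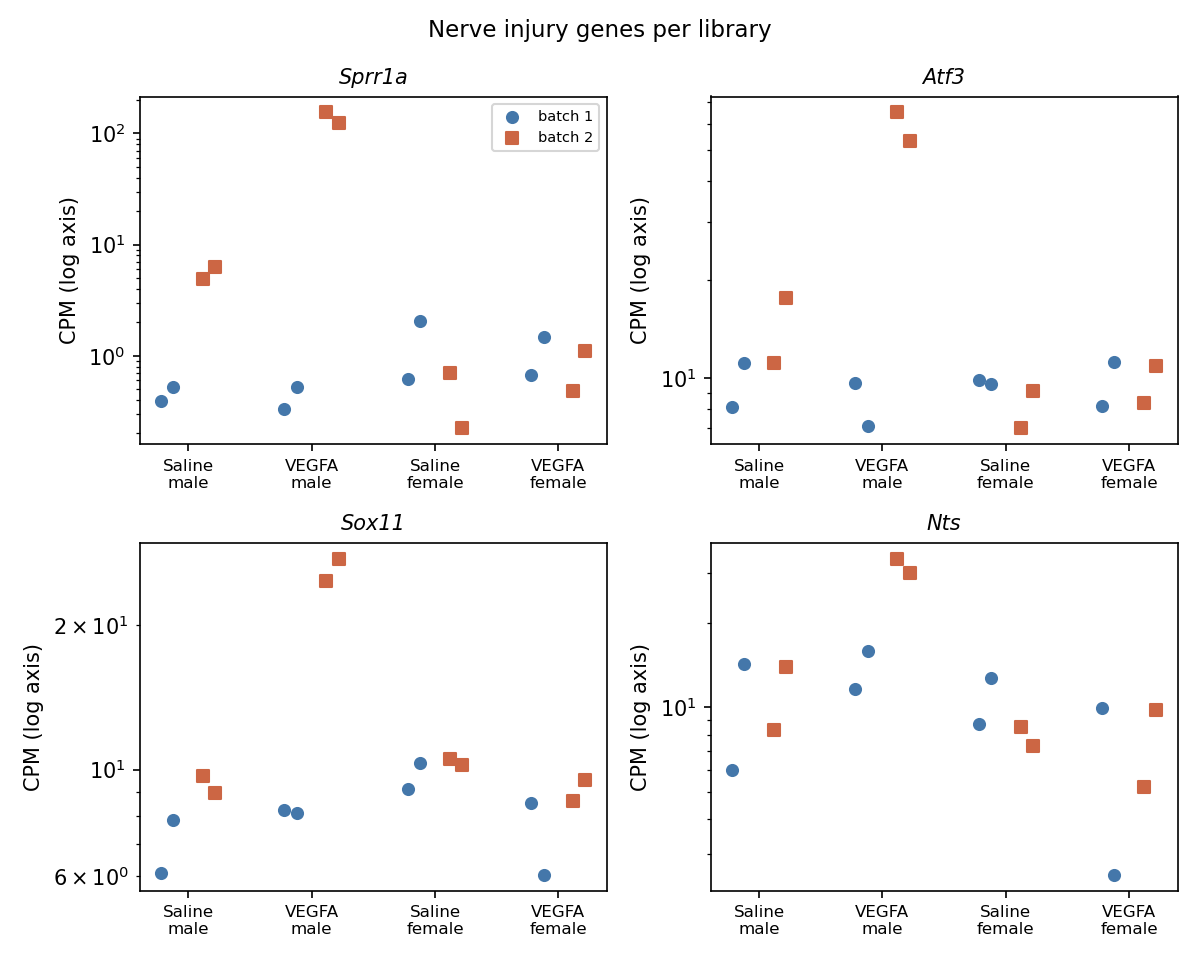
CPM of the nerve injury genes Sprr1a, Atf3, Sox11 and Nts in each library on a log axis, by group and batch. The 2 VEGFA males of batch 2 held the highest values of all 4 genes.

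In females, the heat shock gene Hspa1l was at 0.273 CPM (SD 0.18) in saline and 2.40 CPM (SD 0.743) in VEGFA animals, a log2 difference of 1.91 (SE 0.342, adjusted p = 0.51 by limma). Lbp, which codes for the lipopolysaccharide-binding protein, stood at 102 CPM (SD 21.5) and 57.8 CPM (SD 6.75) (log2 difference -0.80, SE 0.16, with -0.69 in batch 1 and -0.90 in batch 2). Angptl4 differed by -0.85 (SE 0.171), Sfrp4 by -0.82 (SE 0.18) and Ryr3 by 0.96 (SE 0.251). The 3 genes of complement C1q lay lower, C1qa by -0.76 (SE 0.226), C1qb by -0.79 (SE 0.229) and C1qc by -0.87 (SE 0.203), the last at 70.4 and 38.8 CPM. Of matrix genes, Col3a1 stood at 387 CPM (SD 86.9) in saline and 250 CPM (SD 49.3) in VEGFA females (-0.62, SE 0.147) and Col6a2 at 233 and 129 CPM (-0.81, SE 0.214). The remaining genes of the named set were Capn11 (-2.58, SE 0.543, 5.18 and 0.302 CPM) and Lgals3bp (-0.54, SE 0.125, 124 and 84.2 CPM), and every gene of this paragraph had an adjusted p of 0.51.

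Of the 875 genes lower in VEGFA females at an unadjusted p under 0.05, 11 were interferon-stimulated genes and 10 antigen presentation genes. Bst2 was at 37.6 CPM (SD 14.8) in saline and 17.2 CPM (SD 0.814) in VEGFA females (log2 difference -1.03, SE 0.251), Rtp4 at 13.2 and 6.13 CPM (-1.03, SE 0.255) and Irf7 at 33.1 and 16.1 CPM (-1.02, SE 0.266). Antigen presentation genes followed, with Tap2 at 34.1 and 20.3 CPM (-0.71, SE 0.191), B2m at 576 and 371 CPM (-0.58, SE 0.194) and H2-D1 at 532 and 382 CPM (-0.45, SE 0.145). Each of these 6 genes had an adjusted p of 0.51 in limma. Of 25 interferon-stimulated genes 23 lay lower (median -0.52, with -0.54 in batch 1 and -0.52 in batch 2, adjusted p = 3.04e-08 by camera), and 11 passed when adjusted over the list alone. All 15 antigen presentation genes lay lower (median -0.59, with -0.90 in batch 1 and -0.35 in batch 2, adjusted p = 1.44e-09), of which 10 passed when adjusted over the list alone. Both lists had an adjusted p = 0.525 with an estimated correlation. In fry the interferon list had an adjusted p of 0.193 for a common direction and 0.0145 for differences in either direction.

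Fibroblast and collagen genes lay lower in VEGFA females (median -0.28, 16 of 18, with -0.16 in batch 1 and -0.52 in batch 2, adjusted p = 9.45e-06 by camera in limma). Macrophage genes did too (-0.39, 16 of 17, with -0.79 and -0.37, adjusted p = 0.000235). Both had an adjusted p = 0.525 with an estimated correlation. Col6a1, Fbln1, Col6a2, Igfbp6, Pi16 and Col3a1 of the first list and the 3 C1q genes of the second passed when adjusted over the list alone. Cytosolic ribosomal protein genes lay lower (median -0.28, 56 of 57, with -0.48 in batch 1 and -0.07 in batch 2, adjusted p = 5.98e-11; adjusted p = 0.764 with an estimated correlation). So did nuclear oxidative phosphorylation genes (-0.22, 38 of 40, adjusted p = 4.92e-06; adjusted p = 0.771 with an estimated correlation). The ribosomal difference was larger in batch 1, where the slope of expression on transcript length also differed. It was 0.0333 and 0.042 in the VEGFA females and -0.188 and -0.229 in the saline females of that batch. Mitochondrially encoded genes lay higher (0.32, 13 of 13, adjusted p = 6.38e-05; adjusted p = 0.698 with an estimated correlation), with mt-Atp8 at 0.74 (SE 0.221). Skeletal muscle genes lay higher (1.56, 17 of 17, adjusted p = 1.14e-12; adjusted p = 0.525 with an estimated correlation). Among them were Myh7 (4.50, SE 0.98, 18.5 CPM with SD 35.6 and 92.6 CPM with SD 79.0) and Neb (2.43, SE 0.763, 76.7 and 285 CPM). The estimated correlation between genes of this list was 0.866. Without Saline female 4 the median was 0.96 for skeletal muscle and 0.14 for mitochondrially encoded genes, the latter 0.18 without VEGFA female 2. The oxidative phosphorylation median was -0.14 without VEGFA female 1, the fibroblast median -0.18 without VEGFA female 6, and the macrophage median -0.24 without Saline female 3 and -0.59 without VEGFA female 5.

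Lists of glia, neurons, channels and further cell types also passed in females. Myelinating Schwann cell genes lay higher (median 0.26, 13 of 14, adjusted p = 0.00404 by camera in limma; adjusted p = 0.764 with an estimated correlation). Voltage-gated sodium channel genes lay higher too (0.25, 11 of 14, adjusted p = 0.0111; adjusted p = 0.698 with an estimated correlation). The same held for glutamate and GABA receptor genes (0.24, 24 of 32, adjusted p = 0.0111; adjusted p = 0.771 with an estimated correlation) and potassium channel genes (0.11, 27 of 37, adjusted p = 0.0318; adjusted p = 0.771 with an estimated correlation). Pan-neuronal genes lay lower (-0.23, 14 of 16, adjusted p = 0.0111; adjusted p = 0.771 with an estimated correlation). Lower too were genes of meninges and perineurium (-0.39, 9 of 12, adjusted p = 0.00964), heat shock genes (-0.15, 17 of 22, adjusted p = 0.0103) and mast cell genes (-0.54, 5 of 6, adjusted p = 0.0393). These 3 lists had an adjusted p = 0.698 with an estimated correlation. Each of these 8 lists lost its call without at least 1 library. The Schwann cell median was 0.40 without VEGFA female 6, and its call was lost without VEGFA female 5 (0.14) or Saline female 3. Lost too were the calls of sodium channels without VEGFA female 1 (0.13) or Saline female 3, of receptors without Saline female 3 or VEGFA female 6, and of pan-neuronal genes without VEGFA female 2 (-0.09) or Saline female 4 (-0.12). Potassium channels had medians of 0.16 without VEGFA female 2 and 0.18 without VEGFA female 5, and lost their call without VEGFA female 1 (0.04), Saline female 3 or VEGFA female 6. Meninges lost it without VEGFA female 5 (-0.23), heat shock genes without Saline female 8, and mast cells without VEGFA female 1 or 6 or Saline female 3 or 8. After correction for transcript length and GC content the sodium channel, receptor and potassium channel lists no longer passed (medians 0.11, 0.10 and 0.05). In batch 1 the slope of expression on transcript length was 0.0333 and 0.042 in the VEGFA females and -0.188 and -0.229 in the saline females.

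In females 0 of 18283 genes passed in limma and 1735 had an unadjusted p under 0.05 (860 higher and 875 lower), against 914 expected. edgeR called 0 genes and DESeq2 called 1, Hspa1l. Of the 46 lists 16 passed with the preset correlation, and 0 with an estimated correlation or by fry in a common direction.

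**Figure D3:**
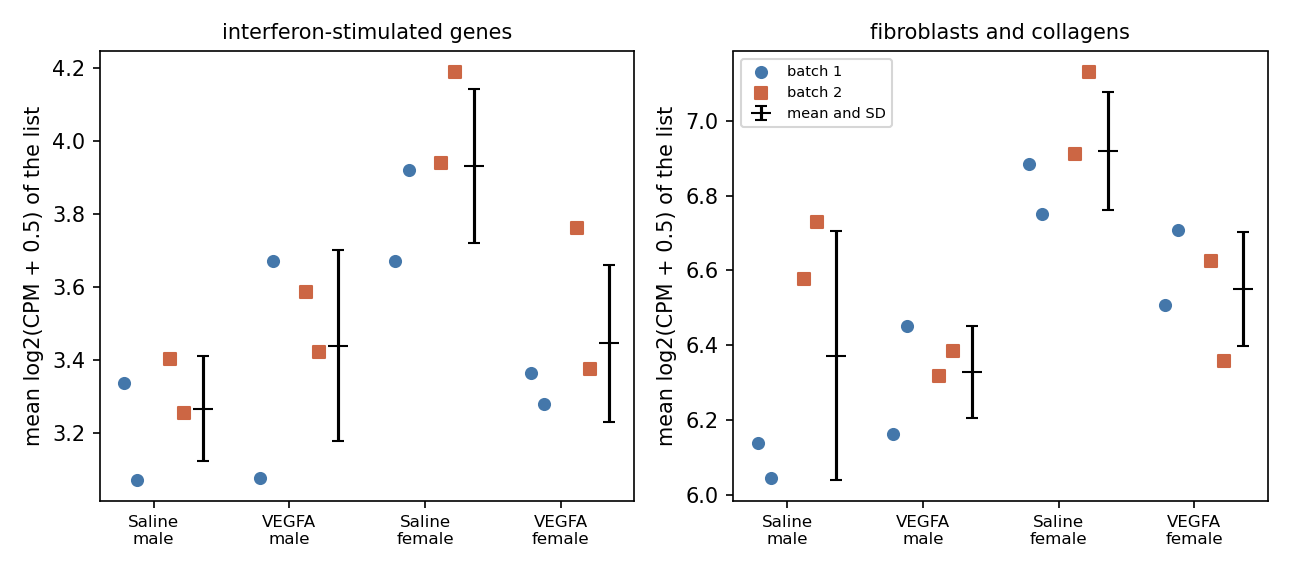
Mean log2 level of the interferon-stimulated genes and of the fibroblast and collagen genes in each library, by group and batch, with the mean and SD of the 4 libraries of a group. The mean of both lists was highest in saline females.

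The direction of the fitted VEGFA difference in males carried little information on that in females. Across 18283 genes the 2 sets of log2 differences had a Pearson correlation of -0.118 and a Spearman correlation of -0.0501, and 49.1% of genes shared a sign. Of genes with an unadjusted p under 0.05 in both sexes, 37 had the same sign and 34 opposite signs, where 47.8 and 47.7 would be expected. In batch 1 VEGFA males share a run of library names with saline females, and saline males with VEGFA females. A difference between these runs would enter the male and female differences with opposite signs and lower their correlation. These values therefore cannot decide whether the sexes share an effect of VEGFA.

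Phlda1 had opposite differences in the sexes, with 13.2 and 21.8 CPM in saline and VEGFA males and 15.5 and 11.1 CPM in saline and VEGFA females (female minus male log2 difference -1.15, SE 0.29). Snrnp48 stood at 15.2 and 24.2 CPM in males and at 23 and 15.3 CPM in females (-1.25, SE 0.308). The injury-linked gene Jun differed by -0.62 (SE 0.175). The interferon and antigen presentation genes Bst2 (-1.40, SE 0.354), Rtp4 (-1.26, SE 0.36) and Tap2 (-1.0, SE 0.27) and the injury gene Sox11 (-1.13, SE 0.371) had lower values for the female difference. Higher were Myh7 (5.87, SE 1.39), Hspa1l (2.02, SE 0.484), Pdk4 (2.73, SE 0.825), Il6ra (1.01, SE 0.321), mt-Atp8 (1.26, SE 0.313) and mt-Nd3 (1.21, SE 0.308). All had an adjusted p of 0.61 in limma, in which 0 of 18283 genes passed and 1497 had an unadjusted p under 0.05 (824 higher and 673 lower). edgeR called 0 genes and DESeq2 called 1, Sox1.

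For interferon-stimulated genes the female difference lay below the male one for 23 of 25 genes (median -0.70, with -0.71 in batch 1 and -0.56 in batch 2, adjusted p = 9.51e-09 by camera in limma), and Rtp4 and Bst2 passed when adjusted over the list alone. Antigen presentation genes had a median of -0.53 (15 of 15, adjusted p = 1.06e-05), with -1.38 in batch 1 and 0.19 in batch 2, and Tap2 passed when adjusted over the list alone. Mitochondrially encoded genes had a median of 0.73 (13 of 13, adjusted p = 3.64e-10), with 8 genes past when adjusted over the list alone. Skeletal muscle genes had a median of 2.07 (adjusted p = 3.51e-10). Nerve injury genes had a median of -0.41 (adjusted p = 0.00112), with 0.03 in batch 1 and -0.91 in batch 2, and Jun passed when adjusted over the list alone. These 5 lists had an adjusted p = 0.632 with an estimated correlation. Spinal cord genes (1.94, adjusted p = 3.94e-05) had an adjusted p = 0.658 with an estimated correlation. Without Saline female 4 the spinal cord median was 1.22, and without Saline female 3 the nerve injury median was -0.26. In all, 17 of 46 lists passed with the preset correlation and 0 with an estimated one or by fry. In batch 1 the female minus male difference coincides with the difference between the 2 runs of library names and cannot be told apart from it.

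In saline animals, Sfrp4 and 2 matrix genes were higher in females than in males. Col3a1, a fibrillar collagen gene, was at 184 CPM (SD 43.1) in males and 387 CPM (SD 86.9) in females (log2 difference 1.08, SE 0.147, adjusted p = 0.0033 by limma, n = 4 per group), with 1.17 in batch 1 and 0.98 in batch 2. Sfrp4 was at 63.9 and 156 CPM (1.29, SE 0.18, adjusted p = 0.0033, with 1.46 and 1.11), and the elastin gene Eln at 25.2 (SD 5.47) and 69.5 CPM (SD 19.9) (1.43, SE 0.244, adjusted p = 0.037, with 1.82 and 1.04). Eln was not called by edgeR, without a batch covariate or without any 1 library of the comparison but Saline male 8 (1.29 to 1.5), Col3a1 not without a batch covariate, and Sfrp4 not with the replicate number as a block (log2 difference 1.29). Col3a1 (ENSMUSG00000026043) lies on chromosome 1 at 45350698 to 45388866 and Eln (ENSMUSG00000029675) on chromosome 5 at 134731447 to 134776177. Other matrix genes did not pass, among them Col5a2 (0.85, SE 0.165, adjusted p = 0.13) and Col5a1 (0.95, SE 0.191, adjusted p = 0.17). Nor did Lbp (0.82, SE 0.16, adjusted p = 0.13), Irf7 (1.23, SE 0.266, adjusted p = 0.26), Bst2 (1.03, SE 0.251, adjusted p = 0.52), H2-K1 (0.71, SE 0.177, adjusted p = 0.52), Igkc (1.94, SE 0.609, adjusted p = 0.84) and Srd5a2 (-2.57, SE 0.525, adjusted p = 0.18).

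Genes of the sex chromosomes followed the labels in all 16 libraries. Xist was listed at 0 in all 4 saline males and at 36.2 CPM (SD 17.2) in saline females (adjusted p = 3.5e-08 by limma), and Ddx3y at 0 in all 8 females and at 5.88 to 13.7 CPM in saline males (adjusted p = 4.2e-06). Eif2s3y (log2 difference -4.74, SE 0.27, adjusted p = 3.5e-08) and Kdm5d (-3.40, SE 0.398, adjusted p = 0.00048) were lower in saline females, while Uty did not pass (-2.02, SE 0.461, adjusted p = 0.35). Kdm5c, an X-linked gene that escapes inactivation, was higher in saline females, at 68.5 CPM against 37.7 CPM (0.87, SE 0.12, adjusted p = 0.0033; not past the threshold with the replicate number as a block). In all, 9 genes passed in limma (5 higher and 4 lower in females), 8 in edgeR and 20 in DESeq2. The ninth was the predicted gene Gm29650, named after its value was seen.

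Interferon-stimulated genes were higher in saline females than in saline males for 25 of 25 members (median 0.64, with 0.49 in batch 1 and 0.77 in batch 2, adjusted p = 1.32e-15 by camera in limma, adjusted p = 0.0131 by fry; adjusted p = 0.0521 with an estimated correlation). Of these genes 9 passed when adjusted over the list alone. Fibroblast and collagen genes were higher for 17 of 18 (median 0.60, with 0.78 and 0.41, adjusted p = 4.84e-13 by camera, 0.017 by fry; adjusted p = 0.058 with an estimated correlation). The same 4 saline female libraries stand in this comparison and in that of VEGFA with saline females. The higher level here and the lower level of VEGFA females there are therefore not 2 independent measurements. In batch 1 saline males and saline females lie in different runs of library names, so sex there cannot be told apart from the run. Antigen presentation genes lay higher (0.58, 15 of 15, with 0.99 in batch 1 and 0.13 in batch 2, adjusted p = 7.04e-11; adjusted p = 0.431 with an estimated correlation). Lists of immune cells lay higher too, with medians of 0.50 for macrophages (15 of 17, with 0.81 in batch 1 and 0.06 in batch 2, adjusted p = 0.000287; adjusted p = 0.459 with an estimated correlation) and 0.78 for T, B and natural killer cells (13 of 13, with 1.60 and 0.20, adjusted p = 5.81e-05; adjusted p = 0.468 with an estimated correlation). Mitochondrially encoded genes lay lower (-0.44, 13 of 13, adjusted p = 5.28e-16; adjusted p = 0.122 with an estimated correlation). Skeletal muscle genes lay lower (-1.09, 17 of 17, adjusted p = 7.23e-12; adjusted p = 0.462 with an estimated correlation). The muscle median was -0.42 without Saline female 4, -0.69 without Saline female 8, -0.70 without Saline male 3 and -1.69 without Saline female 3. With batch as a covariate, the 5 genes of X inactivation and escape were the only list to pass every test (median 0.87, adjusted p = 1.6e-13; adjusted p = 0.0126 with an estimated correlation; 8.09e-05 by fry). In all, 22 lists passed with the preset correlation, 1 with an estimated one and 3 by fry. With the replicate number as a block, a test chosen after the data were seen, 22, 2 and 2 lists passed by these tests. The adjusted p of the interferon list was then 1.72e-14 by camera, 0.13 with an estimated correlation and 0.0833 by fry, and that of the fibroblast list 4.23e-14, 0.033 and 0.0156.

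In VEGFA animals, Sfrp4 was again higher in females, at 88.9 CPM against 40.9 CPM in males (log2 difference 1.10, SE 0.18, adjusted p = 0.024 by limma, with 0.85 in batch 1 and 1.35 in batch 2). It was not called by edgeR, with median-of-ratios scaling, without a batch covariate, without a trend or filter, with batch 2 alone, with only the libraries of the comparison, after length and GC correction or with the replicate number as a block. Nor was it called when VEGFA male 1, 5 or 6 or VEGFA female 1, 2 or 5 was left out (log2 differences 0.92 to 1.15). Eif2s3x, on chromosome X at 93232313 to 93256468, was higher in females (1.29, SE 0.205, adjusted p = 0.019). It was not called without a batch covariate, filter or trend, with batch 2 alone, with only the libraries of the comparison, with the muscle and spinal cord covariates, with the replicate number as a block, or when VEGFA male 1 or 2 or VEGFA female 1 or 2 was left out (1.10 to 1.28). Xist was higher and Eif2s3y (-4.98, SE 0.27, adjusted p = 1.6e-08), Kdm5d (-3.59, SE 0.398, adjusted p = 0.00022) and Uty (-2.98, SE 0.461, adjusted p = 0.016) were lower in females. Ddx3y stood at 7.30 to 28.9 CPM in VEGFA males and was listed at 0 in VEGFA females (adjusted p = 3.5e-07), and Xist at 0 to 0.369 CPM and 18.6 to 95 CPM (adjusted p = 8.2e-08). With Gm29650, a name taken up after its value was seen, 8 genes passed in limma (3 higher and 5 lower in females), 7 in edgeR and 27 in DESeq2.

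Of genes short of the threshold in VEGFA animals, the adipocyte gene Cfd was at 60.1 CPM (SD 19.7) in males and 336 CPM (SD 221) in females (log2 difference 2.35, SE 0.417, adjusted p = 0.054 by limma) and the deiodinase gene Dio2 at 1.69 and 13.4 CPM (2.67, SE 0.477, adjusted p = 0.054). Cyp2e1 (1.68, SE 0.32, adjusted p = 0.1), Pecam1 (0.70, SE 0.145, adjusted p = 0.23) and Il6ra (1.02, SE 0.227, adjusted p = 0.27) lay higher in females. The neuropeptide genes Nts (-1.70, SE 0.389, adjusted p = 0.35), Gal (-1.11, SE 0.314, adjusted p = 0.42) and Tac1 (-0.68, SE 0.212, adjusted p = 0.42; -0.42 without VEGFA female 2), with Serpina3n (-0.64, SE 0.139, adjusted p = 0.25) and Phlda1 (-0.94, SE 0.205, adjusted p = 0.25), lay lower in females. Nts stood at 33.8 and 30 CPM in VEGFA males 5 and 6, against 11.6 and 15.9 CPM in VEGFA males 1 and 2. Gal stood at 58.6 and 54.2 CPM in the former and 29.4 and 33.7 CPM in the latter. Nerve injury genes lay lower in VEGFA females than in VEGFA males for 18 of 20 (median -0.59, with -0.20 in batch 1 and -0.68 in batch 2, adjusted p = 4.72e-12 by camera; adjusted p = 0.131 with an estimated correlation). Of these, 10 passed when adjusted over the list alone. Adipocyte genes (median 1.58, 11 of 13 higher, adjusted p = 2.19e-06) and endothelial genes (0.43, 15 of 17 higher, adjusted p = 9.81e-05) lay higher and nuclear oxidative phosphorylation genes lower (-0.22, 36 of 40, with -0.63 in batch 1 and 0.13 in batch 2, adjusted p = 1.69e-10). These 3 lists had an adjusted p = 0.627 with an estimated correlation, and without VEGFA male 1 the last median was -0.11. The X list passed again (0.77, adjusted p = 7.61e-10; adjusted p = 0.0443 with an estimated correlation). In all, 14 lists passed with the preset correlation, 1 with an estimated one and 1 by fry. Interferon-stimulated genes were not among the 14 (-0.09, adjusted p = 0.289 by camera). In batch 1, sex within VEGFA animals coincides with the 2 runs of library names and cannot be told apart from them.

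The first principal component held 35% of the variance between the libraries. Across the 16 libraries it followed the slope of expression on transcript length (r squared 97.2%, and 92.5% within batches), while batch accounted for 63% of it and group for 11%. The slope of expression on transcript length averaged -0.138 (SD 0.122) in batch 1 and 0.138 (SD 0.0853) in batch 2 (n = 8 each). In batch 1 the slope was -0.288 and -0.228 in the 2 VEGFA males, and in batch 2 it was 0.235 and 0.234.

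**Figure D4:**
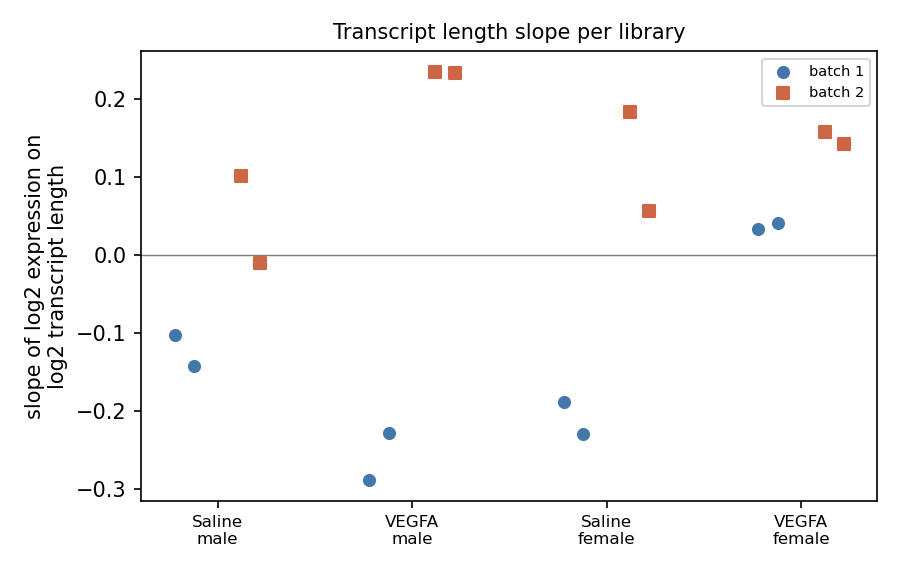
Slope of log2 expression on log2 transcript length in each library, by group and batch. Values below 0 mean that short transcripts stood higher than in the mean of all libraries.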

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

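The test of a VEGFA effect common to both batches of males, the exact permutation tests of list means, the tests of a batch-dependent difference and those in pairs of saline animals were chosen only after the result was seen. So were the length and GC correction and the muscle and spinal cord covariates as settings. Of 412 sets of 4 libraries, 24 had 1 library far from the other 3, and chance gives about 1 in 20, or 21.

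In males, Saline male 8 had a spinal cord list mean of 1.5 (4.29 to 4.62 in the other saline males, log2 CPM) and Eln at 33.3 CPM (21.9 to 23.6), and Saline male 7 had Cfd at 230 CPM (81.5 to 106). Among VEGFA males, number 2 had Nfil3 at 4.50 CPM (7.23 to 7.72), number 5 Neb at 333 CPM (45.4 to 80.7) and Srd5a2 at 10.3 CPM (1.73 to 2.46), and number 1 Snrnp48 at 26.9 CPM (22.9 to 23.6). In saline females, number 3 had a glucocorticoid-responsive list mean of 6.00 (5.81 to 5.84), Nfil3 at 19.4 CPM (10.9 to 11.8), Myh7 at 71.9 CPM (0.444 to 1.01) and Igkc at 564 CPM (129 to 185). Number 7 had a Schwann cell list mean of 7.81 (7.49 to 7.52), Cx3cl1 at 30.9 CPM (22.1 to 23.4), Kdm5c at 71.9 CPM (67.2 to 67.5) and Eif2s3y at 0.297 CPM (0 in the others). Number 4 had Bst2 at 59.6 CPM (28.4 to 32.5), and number 8 Kdm5d at 0.0277 CPM (0 in the others) and Srd5a2 at 1.03 CPM (0.216 to 0.35). Among VEGFA females, number 5 had Ino80d at 34.6 CPM (16.1 to 19) and Sfrp4 at 123 CPM (75.4 to 80.7). Number 2 had Flt1 at 70.5 CPM (44.4 to 45.3), Myh7 at 211 CPM (48.1 to 60.9), Cfd at 664 CPM (183 to 260) and Kdm5d at 0.199 CPM (0 in the others).

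For 17 lists the VEGFA difference in females differed from that in males with the preset correlation and not with an estimated one. The median female minus male difference was positive for skeletal muscle (2.07, adjusted p = 3.51e-10; adjusted p = 0.632 with an estimated correlation), spinal cord (1.94, 3.94e-05; 0.658), mitochondrially encoded genes (0.725, 3.64e-10; 0.632), adipocytes (0.721, 0.00401; 0.774), Schwann cells (0.398, 0.00189; 0.658), glutamate and GABA receptors (0.269, 0.0116; 0.774), hypoxia and glycolysis (0.245, 0.0144; 0.632) and endothelial cells (0.205, 0.0376; 0.759). It was negative for interferon-stimulated genes (-0.698, 9.51e-09; 0.632), meninges and perineurium (-0.548, 0.00533, 0.632), antigen presentation (-0.528, 1.06e-05, 0.632), nerve injury (-0.41, 0.00112, 0.632), pan-neuronal genes (-0.366, 0.00189, 0.658), fibroblasts (-0.341, 0.00253, 0.632), ribosomal proteins (-0.211, 0.000796, 0.778), heat shock genes (-0.185, 0.00189, 0.632) and oxidative phosphorylation genes (-0.18, 0.00372, 0.778). All p-values of this paragraph come from camera in limma. In batch 1 the female minus male difference cannot be told apart from the 2 runs of library names.

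Nerve injury genes stood high in both VEGFA males of batch 2. Sprr1a, a gene outside the naming rule in this comparison and chosen after its values were seen, was at 155 and 124 CPM in these 2 animals, at 4.92 and 6.33 CPM in the saline males of the batch and at 0.222 to 2.04 CPM in the other 12 libraries. The median difference of the list was 0.978 in batch 2, at percentile 100 of 10000 lists matched for length and GC content (central 95% from -0.278 to 0.0893), which argues against length or GC bias. Skin tissue is argued against by the keratins, whose highest ratio over the other libraries of the batch was 0.632 (Krt14). Krt14 was at 0.316 to 0.426 CPM against 0.499, Krt10 at 2.16 to 3.06 CPM against 5.36, and Krt5 at 0 in all libraries of the batch. A VEGFA effect common to both batches of males would raise the list in batch 1 too, where its median was -0.0866. VEGFA and saline males of batch 1 lie in different runs of library names, so this median alone cannot exclude such an effect. Sprr1a lay within 0.222 to 2.04 CPM in both runs of batch 1, so for this gene a rise like that of batch 2 was absent. Something particular to these 2 animals, such as an injury of a nerve, may underlie the values, and this was not tested. They are the only VEGFA males of the batch, so an effect of VEGFA in this batch alone cannot be told apart from it.

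Interferon-stimulated genes stood lower in VEGFA than in saline females (median -0.519; mean of the list -0.485, SE 0.134). A different share of macrophages is argued against as the whole cause, since the median was -0.543 with the macrophage score as a covariate (mean -0.42, SE 0.17), as is 1 deciding library, since the value nearest 0 was -0.436, without Saline female 4 (SE 0.15). Length and GC bias is argued against likewise, with a median of -0.461 after correction (mean -0.492, SE 0.134). Chance stays open, with an adjusted p = 0.525 with an estimated correlation in camera and an exact permutation p of 0.057 (adjusted p = 0.17 over 6 tests) for list means of 3.45 (SD 0.215) and 3.93 (SD 0.211). An effect of VEGFA in females and a high level particular to the 4 saline females, which also exceeded saline males (exact p of 0.029, the smallest possible, adjusted p = 0.17), could each give this pattern. That p ignores batch and the numbers shared by saline males and females. Within the 4 same-numbered pairs the mean difference was 0.663 (SE 0.138, from 0.336 to 0.933), with a p of 0.125 from 16 sign changes, the smallest they can give.

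In males 898 genes had a VEGFA difference that differed between the batches (589 higher in batch 2), and in females 0 did, with 4657 and 2173 at an unadjusted p under 0.05 in limma. Between VEGFA and saline the same fit called 770 genes in batch 1 and 0 in batch 2 in females, and 70 and 3 in males. After length and GC correction 210 passed, 190 of them among the 898. The median size of the 898 differences went from 1.31 (SE 0.307) to 0.952 (SE 0.264), so that calls ended because the differences shrank by more than their SE did, and 72.4% of the median size was left. The fall from 898 to 210 met the criterion fixed before the test for a bias by length and GC content, which looked at the number alone. The size left was weighed beside it, a condition outside that criterion. Whether such a bias underlies these differences therefore stays open. Across genes the difference correlated with log2 length (Pearson 0.349, Spearman 0.41), and median lengths were 4918 bases for genes higher and 1239.5 bases for genes lower, against 3010.5 bases for all. With the muscle and spinal cord scores as covariates 2036 genes passed, all 898 included, so these scores did not account for the whole of the differences. A count also rises where covariates lower the residual spread, and the sizes of the differences were not compared. A part played by such tissue therefore stays open. Sprr1a (5.16, adjusted p = 0.026) and Atf3 (2.40, adjusted p = 0.033) passed after the correction, so their difference is not accounted for by the linear trend. In batch 1 the library names formed 2 runs, VEGFA males with saline females and saline males with VEGFA females. The slopes on transcript length were -0.288 to -0.188 in the former and -0.142 to 0.042 in the latter. In batch 1, treatment within a sex, sex within a treatment and the female minus male difference cannot be told apart from these runs. VEGFA against saline over both sexes is balanced over them.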

How the results depend on the processing

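The settings with length and GC correction, with muscle and spinal cord covariates, and without 2 VEGFA males, the replicate block for lists, and all tests of a batch-dependent VEGFA difference, were chosen only after the data were seen; the other settings were planned. Of 116 results for single genes, 69 kept their direction and their side of the threshold in every setting run for them, and of 51 results for lists 2 did, the X-inactivation list in saline and in VEGFA animals. Most of the gene results had not been called in the main fit, so that keeping their side mostly means staying short of the threshold. The list results held many calls that could be lost, so the counts for genes and lists are not alike. Counted by fit, gene results were the same in 3044, lost their call in 61, gained one in 59 and reversed in 31, and list results were the same in 948, lost their call in 204, gained one in 0 and reversed in 17. Where no reason is given below, the cause was not tested.

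The number of lists past the threshold between VEGFA and saline depended on the correlation assumed between the genes of a list. It was 0 with an estimated correlation and 0 by fry in males, in females, over both sexes and for the female minus male difference.

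The number of genes depended on the tool and the filter. DESeq2 called 1 gene in males, 1 in females, 4 over both sexes, 1 for the female minus male difference, 20 between the sexes in saline and 27 in VEGFA animals. Without a filter 1 gene, Bdkrb1, passed in males. With arrayWeights 24 genes passed between the sexes in saline and 14 in VEGFA animals, and in males Vegfa (0.0934), Flt1 (-0.049) and Kdr (0.0465) reversed.

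With batch 1 alone, 7 genes passed in females, 923 for the female minus male difference, 4 between the sexes in saline and 875 in VEGFA animals. The lists numbered 17 in males and 5 over both sexes. Of these comparisons, only that over both sexes can be told apart from the 2 runs of library names in this batch. Sprr1a (-0.0565), Atf3 (-0.187) and the nerve injury list (-0.0866) reversed in males, Nrp1 in females (0.0467) and over both sexes (0.0174), the fibroblast list over both sexes (0.0249), and the nerve injury list for the female minus male difference (0.0314). With batch 2 alone, 14 genes passed in males, 6 in females (all of slow muscle, Myh7 among them), 8 for the difference and 18 between the sexes in VEGFA animals. Those in males included Atf3, Sprr1a, Malat1, mt-Rnr1, mt-Rnr2, Rn18s-rs5 and the slow muscle genes Myh7, Tnnc1, Tnni1 and Tnnt1. The lists numbered 27 in males and 18 over both sexes. Reversed in that setting were Vegfa (0.479), Flt1 (-0.0691), Kdr (0.365) and the glucocorticoid-responsive list (0.0882) in males, Kdr in females (-0.0108), the glucocorticoid-responsive list over both sexes (0.144), the antigen presentation list for the difference (0.193) and the oxidative phosphorylation list between the sexes in VEGFA animals (0.134).

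With the muscle and spinal cord list means as covariates 4 lists passed in males. By construction the covariates removed most of their own lists, which reversed: the cord list in males (0.00869) and for the difference (-0.0701), and the muscle list in females (-0.152), for the difference (-0.165) and between the sexes in saline (0.0837). Vegfa (-0.044), Kdr (-0.17) and Nrp1 (0.0386) reversed in females, and Vegfa (-0.06) and Kdr (-0.0903) over both sexes. A batch-dependent VEGFA difference passed for 2036 genes in males with these covariates and 35 in females (898 and 0 without), and for 210 in males with length and GC correction.

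Without VEGFA males 1 and 2, 3 genes passed in males, Atf3, Sox11 and Sprr1a, and the lists numbered 17 in males and 17 over both sexes. Vegfa (0.469) and Kdr (0.586) reversed in males and the oxidative phosphorylation list between the sexes in VEGFA animals (0.0518). Without VEGFA males 5 and 6, 5 lists passed over both sexes and 1076 genes between the sexes in VEGFA animals. Sprr1a (-1.13), Atf3 (-0.411), Nrp2 (-0.0366) and the nerve injury list (-0.0926) reversed in males, Vegfa (-0.136), Kdr (-0.154), the ribosomal list (0.00419) and the oxidative phosphorylation list (0.0457) over both sexes, and the nerve injury list for the difference (0.201).

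With 1 library left out at a time, 0 genes passed in males. In females the range was 0 to 5, with 5 without Saline female 3 (Myh7, Myl3, Tnnc1, Tnni1 and Tnnt1, all of slow muscle) and 1 without Saline female 8 (Capn11). Over both sexes it was 0 to 1, with Angptl4 past the threshold without VEGFA female 5 (-0.833), and for the female minus male difference 0 to 5, with the same 5 muscle genes without Saline female 3. Between the sexes it was 8 to 14 in saline animals, 14 without Saline male 8, and 5 to 8 in VEGFA animals, 5 without VEGFA female 2. The lists in males numbered 4 (without Saline male 7) to 19 (without Saline male 4), with 11 without VEGFA male 1. Over both sexes they numbered 7 (without VEGFA female 1) to 18 (without Saline male 4), with 17 without VEGFA female 5. They numbered 11 to 22 in females and 15 to 20 for the difference. In males the ranges were -0.262 to 0.128 for Vegfa, -0.0687 to 0.0995 for Flt1, -0.304 to 0.288 for Kdr and -0.194 to -0.0146 for Nrp1, and in females -0.167 to 0.0165 for Nrp1.

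Of the genes called between the sexes in saline, Eln (1.04 to 1.82 over all settings) lost its call when any library of the comparison other than Saline male 8 was left out, and also without filter, with median-of-ratios scaling, without a batch covariate, with either batch alone, without a trend, with the muscle and spinal cord covariates and in edgeR. Col3a1 (0.97 to 1.17) lost it without a batch covariate and with either batch alone, Sfrp4 (1.11 to 1.46) with batch 2 alone and with the replicate block, and Kdm5c (0.69 to 1.05) without a batch covariate, with either batch alone and with the replicate block, which gave 8 genes in all. The block changed no other call of a named gene in saline animals. In VEGFA animals Sfrp4 (0.85 to 1.35) lost its call when any library but VEGFA male 2 or VEGFA female 6 was left out. It lost it also without filter, with median-of-ratios scaling, without a batch covariate, with batch 2 alone, without a trend, with only the libraries of the comparison, after length and GC correction, without VEGFA males 1 and 2, and in edgeR. Eif2s3x (0.77 to 1.81) lost it without VEGFA male 1 or 2, both of them, or VEGFA female 1 or 2. It lost it also without filter, without a batch covariate, with batch 2 alone, without a trend, with only the libraries of the comparison and with the muscle and spinal cord covariates. Uty lost it without any 1 of the females or VEGFA male 5 or 6, without filter and with batch 2 alone, and was not tested at a mean of at least 2 CPM. In saline animals Kdm5d lost its call with batch 1 alone.

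In VEGFA animals the numbers shared by males and females gave weaker signs of a pairing. The correlations were 0.0948, 0.247, 0.16 and 0.258, not all highest for the own number. In saline animals number 8 also correlated highest with another number. Within batches the correlations were 0.0219 and 0.00996 in VEGFA animals and 0.316 and 0.254 in saline animals. The replicate block gave 12 genes in VEGFA animals, with Car3, Cd36, Cfd, Lpl, Pdk4 and Plin4 gained and Eif2s3x and Sfrp4 lost. No paired analysis was possible for VEGFA against saline because the 2 treatments share no replicate number.

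Depth set the floor of detection: 3 reads correspond to 0.0728 to 0.119 CPM. Xist in males and the Y-linked genes in females largely lay at or near this floor, so that their fitted differences depend on the pseudocount. Among the values above it were Xist at 0.267 and 0.369 CPM in VEGFA males 5 and 6 and Eif2s3y at 0.297 CPM in Saline female 7.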

Other observations

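The tests of a batch-dependent difference were chosen only after the result was seen, as was the count of splits for genes outside the sex chromosomes, and the other splits were planned. Of the neuronal lists, those of pan-neuronal genes, voltage-gated sodium channels, glutamate and GABA receptors and potassium channels passed in females (adjusted p = 0.0111, 0.0111, 0.0111 and 0.0318 by camera with the preset correlation). With an estimated correlation 0 lists passed in females, and the channel and receptor lists no longer passed after length and GC correction. The lists that follow did not pass in either sex. Medians in males and females were 0.12 and -0.07 for peptidergic nociceptors (adjusted p = 0.204 and 0.334 by camera in limma), 0.02 and 0.03 for non-peptidergic and pruriceptive neurons (0.688 and 0.504), and 0.13 and -0.02 for low-threshold mechanoreceptors and proprioceptors (0.173 and 0.874). They were 0.01 and 0.04 for TRP, ASIC and mechanically gated channels (0.424 and 0.816), -0.15 and -0.01 for purinergic receptors (0.173 and 0.928), -0.20 and -0.02 for opioid and cannabinoid signalling (0.126 and 0.944), and 0.03 and 0.04 for calcium and HCN channels (0.496 and 0.928). Satellite glia (-0.35 and 0.11, adjusted p = 0.214 and 0.928), mural cells (-0.03 and 0.02, 0.534 and 0.646) and sex hormone receptors (-0.07 and 0.09, 0.441 and 0.61) did not pass either.

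Several lists of blood and immune cells had medians of opposite sign in the 2 batches. Each of these medians comes from 2 against 2 libraries, and the difference between batches was not tested for these lists. In batch 1 VEGFA males share a run of library names with saline females, and saline males with VEGFA females. Opposite signs in males and females of that batch therefore cannot be told apart from a difference between the runs. The neutrophil and bone marrow list had medians of 1.19 in batch 1 and -0.93 in batch 2 in males and -1.68 and 0.97 in females (adjusted p = 0.775 and 0.435 in camera over both batches). Cell cycle genes went the same way, with 0.69 and -0.64 in males and -0.77 and 0.54 in females (adjusted p = 0.663 and 0.447), and so did T, B and natural killer cell genes, with 0.73 and -0.70 in males and -1.24 and 0.22 in females (0.931 and 0.173). In females the batches agreed in sign for macrophages (-0.79 and -0.37), mast cells (-0.75 and -0.25), antigen presentation (-0.90 and -0.35) and cytokines and chemokines (-0.36 and -0.17). In males these 4 lists had opposite signs, with 0.43 and -0.56, 0.09 and -0.88, 0.44 and -0.58, and 0.42 and -0.48. Interferon-stimulated genes agreed in sign in females (-0.54 and -0.52) and in males (0.14 and 0.13). VEGFA male 1 held genes of sympathetic neurons and cartilage, chosen after their values were seen: Dbh at 43.0 CPM, Slc6a2 at 13.3 CPM, Hand2 at 5.81 CPM, Col2a1 at 138 CPM and Acan at 31 CPM.

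Single genes of the VEGFA males of batch 2 were compared with limma for each batch. Of the nerve injury list, Sprr1a had log2 differences of -0.06 in batch 1 and 4.52 in batch 2 (difference 4.57, SE 0.657, adjusted p = 0.024) and Atf3 of -0.19 and 2.03 (2.22, SE 0.408, adjusted p = 0.024). Cacna2d1 of the list differed by 1.91 (SE 0.31, adjusted p = 0.024) and Npy1r, which is not of the list, by 2.20 (SE 0.454, adjusted p = 0.029), both chosen after their values were seen. Sox11 did not pass (1.21, SE 0.344, adjusted p = 0.056), and in females Sprr1a (0.59, adjusted p = 0.76) and Atf3 (0.26, adjusted p = 0.84) did not. In the 2 animals Nts stood at 33.8 and 30 CPM (2.54 to 15.9 in the other libraries), Sox11 at 24.7 and 27.5 CPM (6.04 to 10.5) and Atf3 at 65.2 and 53.3 CPM (6.99 to 17.6).

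Other splits of the same libraries were fitted to see where chance can be excluded. In the sex comparisons only 1 of 35 splits, the real one, gave 9 genes in saline (highest other 5) and only 1 of 35 gave 8 in VEGFA animals (highest other 1). Genes of the X and Y chromosomes, which must part by sex, fixed these counts, so they decide nothing for the other genes. Outside the sex chromosomes chance cannot be excluded: as many as the real 3 genes passed in 2 of 35 splits in saline (highest other 5), and as many as the real 1 in 2 of 35 in VEGFA animals (highest other 1). Of the 8 splits of saline libraries that part all 4 same-numbered pairs, the other 7 gave 0 genes, and these splits are too few for a share under 0.05. For VEGFA against saline the splits decide nothing, because the real count of genes was 0 and every split reaches it by construction: 35 in males (highest other 0), 35 in females (highest other 2) and 100 over both sexes (highest other 0). The same holds for the 100 splits of the female minus male difference. There 3 of the 100 splits gave any gene, with 1431, 1099 and 1, and the 2 large counts point to a structure of the samples, whose nature was not tested. These 3 splits were not balanced over the batches, and the 27 balanced splits, the real one included, gave 0 genes.

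For the lists with the preset correlation chance cannot be excluded. As many as the real 7 lists passed in 29 of 35 splits in males (highest other 29), among them the split by batch with 14, and as many as 16 in 16 of 35 in females (highest other 29), where the split by batch gave 15. As many as 11 passed in 66 of 100 splits over both sexes (highest other 30) and as many as 17 in 29 of 100 for the female minus male difference (highest other 31).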
